A study of Mus musculus with 8 samples.

How the data were processed

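Nuclei of lineage-negative, Sca1-positive, ckit-positive (LSK) bone marrow cells, a fraction that holds hematopoietic stem cells and early progenitors, were profiled with the 10x multiome assay. The labels name 8 samples from WT mice and from littermates with the T58A point mutation of MYC: 4 RNA and 4 chromatin accessibility (ATAC) samples, 2 per genotype and assay, each from 2 mice. The ATAC samples were not used here. The processing notes name Cell Ranger ARC, Seurat and Signac with the build mm10. Their versions, the gene annotation and the filters on nuclei were not given in the sources used here. The deposited table holds UMI counts, with no normalization, for 32285 genes in 8708 nuclei. Its values were checked to be whole numbers.

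Barcodes carry a suffix from 1 to 4, which makes 4 barcode sets. No label, header or other table used here ties a suffix to a genotype or a replicate, and none was inferred from the values. The deposited counts are named for T58A alone, so it was not certain that they also hold WT nuclei. T58A and WT were therefore not compared, and the tests fixed for that comparison (edgeR on sums per sample, camera, permutation tests) were not run. As fixed before the data were examined for this case, the whole table was treated as 1 sample, with no p-value made from nuclei. Values per barcode set are given beside it ungrouped, and the sets are not called replicates. The table has 0 further columns of per-sample values that were left unused.

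Counts were scaled to 10000 UMIs per nucleus and log-transformed, and 2000 variable genes were taken by dispersion, without sex-linked and mitochondrially encoded genes. Values were scaled per gene, limited to 10 SDs, and reduced to 30 principal components. Clusters came from a shared-neighbour graph with 15 neighbours and Leiden clustering at resolution 0.8. The mean of each barcode set was removed from the components, a step fixed for the case that clusters followed replicates and used here for the sets. They did: Cramer's V between clusters and sets was 0.341 with the means kept and 0.145 with them removed. All nuclei were kept as deposited. A doublet score, the share of simulated doublets among a nucleus's neighbours, marked the highest 5% per set for an alternative only.

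A cluster took the name of a cell type when at least 3 genes of a marker list fixed beforehand were detected in at least 5% of its nuclei at 2 or more times the level of other nuclei. There were 12 marker lists, named with their classes in the results, and 18 lists of other gene groups. The 2 clusters that took the name of the megakaryocyte-erythroid list were told apart, after their markers were seen, as megakaryocyte-side and erythroid-side. A cluster led by immunoglobulin genes, and a cluster that met 2 marker lists, were left unnamed. Names end in "-like" because they rest on markers alone. The 5 genes named for a cluster are those with the largest ratio of counts per 1000000 UMIs (CPM, plus 10) to all other nuclei, among genes detected in at least 20% of its nuclei.

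The gene lists, marker lists and the rules for named genes were also fixed then, while the comparison of classes with HSC-like nuclei and the 1.5-fold rule were chosen after the clusters were seen. Each progenitor class was compared with the HSC-like nuclei on sums of counts as CPM plus 10. Genes with at least 50 counts over both groups were measured. A gene was called higher or lower when the ratio reached 1.5-fold with the same direction in all 4 barcode sets, a description and not a test. The 10 highest and 10 lowest ratios among genes with at least 200 counts were taken as named genes, mitochondrially encoded genes left out. The 2 members with the largest ratio were named per gene list, and any other member named was chosen after its values were seen. Not every gene that these rules pick is named in the results. A list's median log2 ratio was placed among 10000 random lists matched on mean expression in 20 bins. Folds printed are ratios of CPM without the added 10. Intervals are at 95%: exact Clopper-Pearson for shares, exact Poisson for CPM and exact binomial for ratios, and these cover counting error only. The limit given for a count of 0 is 3 counts of the total, which lies below the upper bound of the exact 2-sided interval. Intervals of list medians are percentiles of 1000 medians over list members drawn with replacement, and those of Cramer's V of 200 values over nuclei drawn with replacement with the clusters held fixed. They cover neither differences between samples nor the clustering.

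S phase and G2/M genes were read as the share of nuclei with at least 2 genes of a list detected, after each nucleus was thinned to 2000 UMIs. Nuclei under 2000 UMIs were left out there. On simulated counts with a spread between sets of 0.2 (SD of the natural log), the 1.5-fold rule found 100% of 50 genes raised 4-fold in each of the 4 classes. Of 50 genes raised 2-fold it found 68% in the lymphoid, 72% in the myeloid, 58% in the megakaryocyte-side and 64% in the erythroid-side comparison. Of decreases it found 92%, 90%, 84% and 78% of 50 genes lowered 4-fold in the same order, and 58%, 60%, 70% and 46% of 50 lowered 2-fold. Of the unchanged genes it called 0.318%, 0.221%, 1.15% and 0.474% in the same order. The simulations ran on 10252, 10129, 9384 and 9901 genes.

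The alternatives changed the resolution (0.4 and 1.2), the number of variable genes (1000 and 4000), the number of components (15 and 50), the nuclei kept (at least 500 genes), the cell cycle genes used, the thinning (1000 UMIs and none) and the genes needed (3). No nucleus had under 1000 UMIs. Further alternatives were chosen after the data were seen: set means kept, gene-list genes left out of the clustering, the marked doublets left out, nuclei with over 40% mitochondrial UMIs left out, CPM over non-mitochondrial UMIs, each barcode set left out, and list members that were neither markers nor variable genes. Gene lengths and positions came from a RefSeq table of GRCm38.p6 (mm10), in which 26660 of the 32285 gene names (82.6%) were found. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used.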

Results

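RNA of 8708 nuclei from sorted LSK marrow cells, in a series of WT and T58A mice, was measured as UMI counts for 32285 genes, of which 9429 had no count. The table held 45723860 UMIs, with a median of 4147.5 per nucleus and a range from 1001 to 24786. Barcode sets 1 to 4 held 2999, 721, 2756 and 2232 nuclei with 11349205, 5786144, 12758644 and 15829867 UMIs. Their median depths were 3035, 6764, 3638.5 and 5930.5 UMIs per nucleus. Mitochondrially encoded genes took 24.6%, 9.98%, 24.2% and 9.22% of their UMIs. The series asked how the T58A mutation of MYC alters these progenitors. The barcode sets could not be tied to a genotype, so the values below describe the kinds of nuclei in the whole table, as 1 sample without replicates.

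The nuclei fell into 18 clusters, and the genes that define each are a description of the clustering, not a finding. HSC-like nuclei expressed Procr, Hlf, Mecom, Fgd5, Mllt3, Rarb and Meis1, genes known from hematopoietic stem cells, and were led by Il1rapl2, at 10.3 times the level of other nuclei, with Magi2, Abcg3, Lhcgr and Mamdc2. Myeloid progenitor-like nuclei were led by the granule protease gene Elane (29.3 times) with F13a1, Mpo, Ms4a3 and Ctsg. Lymphoid progenitor-like nuclei formed 2 clusters, both led by Cmah, Dntt, Arpp21 and Fgf13, joined by Il12a in the larger and by the interleukin-7 receptor gene Il7r in the smaller. Megakaryocyte-side nuclei were led by Vwf (13.1 times), Rab27b, Itga2b, Plcb1 and Myom1 and also carried Pf4. Erythroid-side nuclei were led by Slc25a21 (66.5 times), Car1, Ermap, Kel and Abcb4 and also carried Gata1, Klf1 and Epor.

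HSC-like nuclei made up 12.1% of all nuclei (1055; 95% interval 11.4 to 12.8%), lymphoid progenitor-like 11.01% (959; 10.4 to 11.7%), myeloid progenitor-like 8.64% (752; 8.05 to 9.25%), megakaryocyte-side 5.96% (519; 5.47 to 6.48%) and erythroid-side 5.87% (511; 5.38 to 6.38%). In barcode sets 1 to 4, HSC-like nuclei took 10.0%, 16.0%, 12.6% and 13.2%, lymphoid progenitor-like 10.3%, 18.4%, 7.15% and 14.4%, and myeloid progenitor-like 7.87%, 12.8%, 7.29% and 9.99%. Megakaryocyte-side nuclei took 6.07%, 6.10%, 6.31% and 5.33%, and erythroid-side nuclei 6.07%, 1.80%, 8.42% and 3.76%. The shares depended on the clustering: the HSC-like share was 6.26% with set means kept and 7.99% with 1000 variable genes, and the megakaryocyte-side share 9.65% without cell cycle genes and 9.18% without barcode set 1. The lymphoid share was 17.1% without barcode set 3, and the myeloid share 13.5% without barcode set 2.

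**Figure D1:**
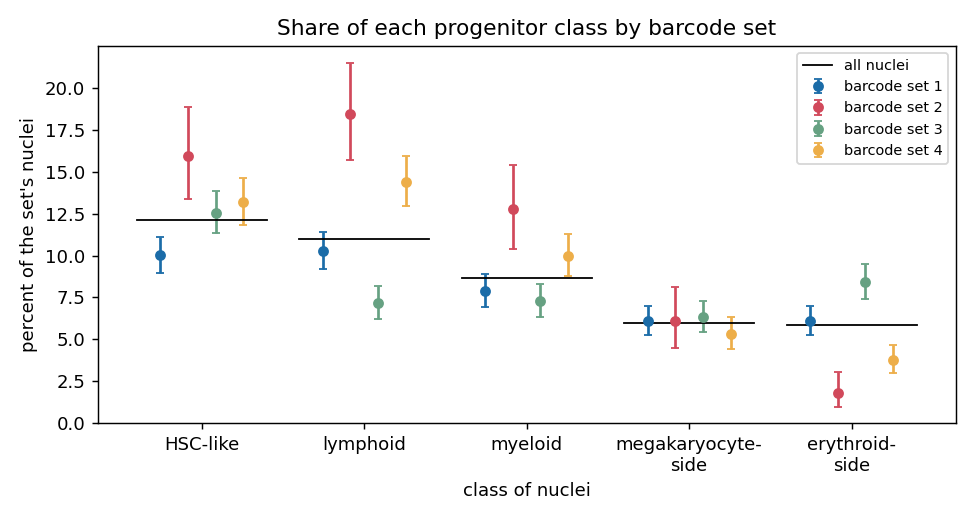
Share of nuclei (percent) in each class for the whole table and for each of the 4 barcode sets, with exact 95% intervals that cover counting error only. HSC-like nuclei made up 12.1% of the whole table, and erythroid-side nuclei ranged from 1.80% to 8.42% between sets.

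Nuclei named by marker lists of mature cell types, which the sort was meant to remove, were present at low shares. The names do not show that these nuclei were mature. At 2000 UMIs per nucleus, B cell-like nuclei, whose markers included Vpreb1 and Igll1, had a median of 11 G2/M genes. Neutrophil-like nuclei had a median of 8, from 27 nuclei, against 3 in HSC-like nuclei. B cell-like nuclei (Ebf1, Pax5, Cecr2, Lef1, Blnk) took 2.49%, monocyte, macrophage and dendritic cell-like nuclei (Plbd1, Cadm1, H2-Aa, Cd74, H2-Eb1) 1.79%, and erythroid cell-like nuclei (Slc4a1, Hba-a1, Hbb-bs, Sptb, Sox6) 1.41%. T and NK cell-like nuclei (Trbc1, Gm36723, Bcl11b, Skap1) took 0.953%, neutrophil-like nuclei (Camp, Ngp, Ltf, S100a9, S100a8) 0.919%, mast cell and basophil-like nuclei (Prss34, Ms4a2, Mcpt8, Cpa3, Hdc) 0.643%, and endothelial and stromal-like nuclei (Stab2, Ldb2, Abcc9, Vcam1, Zfpm2) 0.138%. No cluster took the name of the eosinophil list. An unnamed cluster of 160 nuclei was led by Igha (205 times), Jchain, Ighm, Igkc and Gm30211, and another of 69 nuclei by Fn1, Thbs1, Lyz2, Ahnak and Gas7. The erythroid cell-like cluster held 67 nuclei of barcode set 1, 56 of set 3 and 0 of sets 2 and 4, which allows shares of up to 0.416% in set 2 and 0.134% in set 4.

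Lymphoid progenitor-like nuclei held 697 genes higher and 945 lower than HSC-like nuclei, of 10246 measured. Dntt, which encodes the polymerase that adds nucleotides at immunoglobulin and T cell receptor joints, was at 807 CPM against 32.9, a ratio of 24.5 (20.9 to 29.1), and Il7r at 196 against 4.39 CPM. Cmah, Arpp21, Fgf13, the B lineage factor gene Ebf1, Col19a1, Atp8b4, Il12a and Irf8 completed the 10 highest. The 10 lowest were Dlg2, Ncam2, Plxdc2, Nbea, Rora, Csgalnact1, Prkg1, Pcdh7, Slc18a2 and Trpc6, with Ncam2 at 2.96 against 133 CPM. All 9 measured HSC markers were lower and 8 of 9 lymphoid progenitor markers higher, which the naming favours. Of the myeloid progenitor markers, 6 of 8 were higher too, Mpo at 321 against 101 CPM. Without barcode set 2 the counts were 366 genes higher and 618 lower.

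Among gene groups in lymphoid progenitor-like nuclei, cell cycle genes were higher, with 41 of 49 G2/M genes (median log2 ratio 1.13), among them Top2a at 528 against 96.7 CPM and Ect2 at 149 against 21.7, and 26 of 42 S phase genes (0.76), among them Brip1 and Clspn. Self-renewal regulators were mostly lower, 13 of 25 against 1 higher (-0.64), with Prdm16 at 23.3 against 232 CPM. Immediate early and stress genes were lower for 8 of 15 and higher for 1 (-0.72, or -1.12 with set means kept), with Fosb at 191 against 539 CPM and Egr1 at 185 against 469. Of the interferon response list 5 of 27 were lower and 0 higher (-0.29), among them the RNA sensor gene Ifih1 at 27.6 against 75.0 CPM and Oasl2 at 17.9 against 42.3, but the median was 0.01 without barcode set 2. Among apoptosis regulators, most of which were neither higher nor lower, Bcl2, which encodes a survival protein, was at 650 against 201 CPM, and Bcl2l11, which encodes the death-promoting protein BIM, at 126 against 38.2. MYC targets were higher for 4 of 55 (Plk4, Mcm4, Mcm5 and Hspe1) and lower for Sord (median 0.20, or 0.13 without barcode set 2). Notch1 was at 267 against 58.1 CPM and Gata3 at 2.56 against 14.5, from a list of Notch targets and T lineage genes too few of which were measured for a median, and Notch1 was also among the markers that named these nuclei.

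Myeloid progenitor-like nuclei held 934 genes higher and 1989 lower than HSC-like nuclei, of 10187 measured. The genes called lower were long, at a median of 46.2 kb against 27.2 kb for all measured genes. In lymphoid, megakaryocyte-side and erythroid-side nuclei they were at 62.4, 48.3 and 45.5 kb against 27.5, 28.9 and 27.5 kb. Genes called higher were at 25.4 kb in myeloid nuclei and at 37.6, 35.9 and 29.4 kb in those classes. The nuclear transcript Malat1 ran from 7492 to 9327 CPM in lymphoid, 9221 to 9978 in megakaryocyte-side and 4898 to 6502 in erythroid-side nuclei of single sets. In myeloid nuclei it ran from 5215 to 6019 CPM, against 11948 to 13332 CPM in HSC-like nuclei. The 10 highest included genes of granule proteins: Mpo, which encodes myeloperoxidase, was at 3486 against 101 CPM (34.6-fold, 31.6 to 38.1), Elane at 622 against 12.1 CPM (51.6-fold, 39.6 to 68.7), and Ctsg at 402 against 10.7. F13a1, Atp8b4, Rab44, Apba1, Nrg2, Irf8 and Ms4a3 were the others. The 10 lowest included Mecom, a transcription factor gene of stem cells, at 135 against 2366 CPM (17.6-fold lower, 16.3 to 19.0), with Trpc6, Samd12, Rora, Il1rapl2, Plxdc2, Dlg2, Prkg1, Klf12 and Csgalnact1. All 11 measured myeloid progenitor markers were higher and all 9 HSC markers lower, which the naming favours.

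In the myeloid progenitor-like nuclei 47 of 51 G2/M genes (median 1.49), such as Top2a at 736 against 96.7 CPM and Kif11 at 279 against 32.2, and 27 of 42 S phase genes (0.80), such as E2f8 and Brip1, were higher. Glycolysis genes were higher for 6 of 15 and lower for 2 (0.51), with Pgam1 at 68.5 against 22.8 CPM and Gpi1 at 150 against 65.1. Glycolysis medians of single barcode sets ran from 0.03 to 0.83. Of the interferon response list 19 of 25 were lower and 0 higher (-1.02), with the RNA sensor gene Ddx58 at 5.55 against 66.4 CPM and Ifi44 at 4.07 against 41.4. Immediate early and stress genes were lower for 12 of 16 (-1.12), with Nr4a1 at 9.44 against 157 CPM and Egr1 at 50.2 against 469, and higher for 2, among them the heat shock gene Hspa1b at 31.8 against 2.63. The NF-kB list was lower for 7 of 14 and higher for 1 (-0.62, or -0.39 without barcode set 2 and -0.36 with 1000 variable genes), with Nfkbiz at 63.7 against 310 CPM and Ccl4 at 10.9 against 37.3. Self-renewal regulators were lower for 17 of 24 and higher for 2 (-1.16). MYC targets were higher for 9 of 56, such as Tmem97 at 49.0 against 10.1 CPM and Plk4 at 67.4 against 19.5, and lower for 2 (0.32), and ribosome biogenesis genes higher for 2 of 24, Nhp2 and Heatr1 (0.20, or 0.32 without barcode set 1 and 0.13 without set 2).

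Megakaryocyte-side nuclei held 565 genes higher and 1172 lower than HSC-like nuclei, of 9527 measured. The 10 highest included genes known from platelets: Pf4, which encodes platelet factor 4, was at 118 against 2.85 CPM (41.5-fold, 23.9 to 78.9), the integrin gene Itga2b at 337 against 34.9 CPM (9.68-fold, 8.16 to 11.5) and Vwf, the gene of von Willebrand factor, at 256 against 29.6 CPM. The others were Mfsd2b, Rab27b, Plcb1 and Chsy3, and Neil3, Ckap2l and Kif15, which are known from dividing cells. The 10 lowest were Ptprm, Myof, Tox, Mamdc2, Hlf, Gimap6, Palld, Ncam2, Prex2 and 9530026P05Rik, with Hlf, a stem cell factor gene, at 156 against 1092 CPM. Other stem cell genes were higher: Gata2 was at 208 against 114 CPM and Tek, the angiopoietin receptor gene, at 73.5 against 44.3. Of all self-renewal regulators 5 of 25 were higher and 9 lower (-0.27), and of the HSC markers 2 of 9 were higher and 5 lower.

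In the megakaryocyte-side nuclei 38 of 44 G2/M genes (median 1.18), such as Ckap2l and Kif11, and 28 of 41 S phase genes (0.82), such as E2f8 and Clspn, were higher. The interferon response list was lower for 16 of 26 and higher for 0 (-0.89), with Oasl2 at 7.80 against 42.3 CPM and Ifi44 at 9.44 against 41.4. The NF-kB list was lower for 9 of 13 and higher for 0 (-0.78, or -0.51 with 1000 variable genes), with Nfkbiz at 69.0 against 310 CPM and Ccl4 at 9.03 against 37.3, and immediate early and stress genes lower for 7 of 14 (-0.64, but -0.36 without barcode set 1 and -0.33 at resolution 1.2), with Zfp36 at 50.1 against 150 CPM. MYC targets were higher for 8 of 54, among them Plk4 and the replication helicase gene Mcm5, and lower for Dusp2 (0.28). Ribosome biogenesis genes had a median of 0.31, or 0.13 with 50 components, with 1 of 23 higher, Bop1.

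Erythroid-side nuclei held 1088 genes higher and 2778 lower than HSC-like nuclei, of 9947 measured. The 10 highest included genes known from red cells: Car1, which encodes carbonic anhydrase 1, was at 1255 against 13.6 CPM (92.3-fold, 71.9 to 121), the mitochondrial carrier gene Slc25a21 at 4022 against 36.0 CPM (112-fold, 95.9 to 131), and the blood group genes Ermap at 397 against 3.51 CPM and Kel at 294 against 2.19. Ank1, Abcb4, Rhag, Gpc4, Aqp1 and Atp7b completed the 10 highest. Mecom was at 96.2 against 2366 CPM (24.6-fold lower, 22.4 to 27.1) and Hlf at 49.0 against 1092, and Il1rapl2, Samd12, Dlg2, Rora, Tbxas1, Klf12, Cacnb2 and Trpc6 completed the 10 lowest. Mitochondrially encoded genes were higher for 12 of 13 (median 1.08), with mt-Nd1 and mt-Nd3 the farthest. Single barcode sets ran from 0.71 to 1.05, all below the pooled value, which also carries the mix of sets. The median of all genes was -0.17 over all UMIs and 0.01 over non-mitochondrial UMIs, a scaling that gave 1758 genes higher and 2327 lower.

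MYC targets were higher in erythroid-side nuclei for 29 of 55 and lower for 2 (median 0.72), with the nucleolar protein gene Nop56 at 387 against 131 CPM and Tmem97 at 45.7 against 10.1, while Dusp2 was at 10.9 against 94.3. Ribosome biogenesis genes were higher for 10 of 24 and lower for 0 (0.56), with Heatr1 at 144 against 60.1 CPM and Nat10 at 101 against 44.3. Over non-mitochondrial UMIs the 2 medians were 0.97, with 36 higher, and 0.79, with 17 higher. G2/M genes were higher for 46 of 51 (1.51), such as Anln at 350 against 22.6 CPM and Hmmr at 146 against 11.8, and S phase genes higher for 22 of 41 and lower for 1 (0.64). The interferon response list was lower for 19 of 26 and higher for 0 (-1.13), with Ifi44 at 1.24 against 41.4 CPM and Trim30a at 19.8 against 110. The NF-kB list was lower for 11 of 13 (-1.42), with Nfkbiz at 28.8 against 310 CPM and Rel at 19.6 against 135. Medians of single barcode sets ran from -1.12 to -0.69 for the interferon and from -1.35 to -1.03 for the NF-kB list. Both pooled medians lay beyond these ranges and also carry the mix of sets. Immediate early and stress genes were lower for 13 of 15 and higher for 1 (-1.67), with Nr4a1 at 10.3 against 157 CPM and Klf6 at 28.4 against 212. Self-renewal regulators were lower for 18 of 25 and higher for 2 (-1.20).

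Among survival and energy genes in erythroid-side nuclei, the anti-apoptotic median lay at percentile 0.53 of matched lists, glycolysis at 16.8, pro-apoptotic genes at 84.7 and oxidative phosphorylation at 99.97. Anti-apoptotic genes were lower for 6 of 8 (median -1.15), with Mcl1 at 50.04 against 184 CPM and Bcl2 at 62.2 against 201, whereas Bcl2 was at 684 CPM in myeloid progenitor-like and 538 CPM in megakaryocyte-side nuclei. Mcl1 was lower in all 4 classes, at 106 CPM in lymphoid, 82.9 in myeloid and 104 in megakaryocyte-side nuclei. Pro-apoptotic genes had a median of 0.05, or 0.20 over non-mitochondrial UMIs, with 2 of 11 higher and 2 lower. Glycolysis genes were lower for 6 of 15 and higher for 1 (-0.39), with Pkm, the pyruvate kinase gene, at 9.68 against 59.2 CPM and the glucose transporter gene Slc2a1 at 1.65 against 24.6. Over non-mitochondrial UMIs the glycolysis median was -0.17 with 5 lower and 2 higher. Oxidative phosphorylation genes had a median of 0.12 with 6 of 72 higher, among them Cox6b2 at 54.4 against 7.67 CPM, and 1 lower, or 0.33 with 13 higher and 0 lower over non-mitochondrial UMIs. That median was 0.23 without barcode set 3 and 0.03 without set 4. Cytosolic ribosomal protein genes were lower for 14 of 81 and higher for 1 (-0.40), but medians of single barcode sets ran from -0.38 to 0.13 with only 2 of 4 below 0. Over non-mitochondrial UMIs 3 were lower and 3 higher (-0.16). The p53 targets had a median of -0.03, or 0.07 over non-mitochondrial UMIs, with 2 of 17 higher (Aen and Psrc1) and 3 lower (Btg2, Trp53inp1 and Plk2).

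Most other lists held few called members, and many of their medians went both ways between single barcode sets. Oxidative phosphorylation had medians of 0.02, 0.25 and 0.05 in lymphoid, myeloid and megakaryocyte-side nuclei, with 1, 5 and 0 members higher, Cox5a in lymphoid nuclei at 40.8 against 22.1 CPM. The myeloid median ran from -0.09 to 0.39 in single barcode sets, was 0.12 without set 2, and had 10 members higher over non-mitochondrial UMIs. Ribosomal proteins had medians of 0.06, -0.01 (0.09 over non-mitochondrial UMIs) and -0.10, and glycolysis -0.01 in lymphoid and -0.04 in megakaryocyte-side nuclei. NF-kB genes in lymphoid nuclei were higher for 5 of 15, such as Ccl4, and lower for 2, such as Tlr4 (0.06, a median that took the other sign in 5 of 18 alternatives), and ribosome biogenesis 0.09 with 0 of 24 called. Pro-apoptotic lists gave 0.10, 0.05 and -0.14, anti-apoptotic lists -0.11, -0.47 and -0.36, and p53 targets 0.04, 0.01 and -0.09. Mitochondrially encoded genes gave 0.07, 0.51 and 0.32. Monocyte and dendritic cell markers were higher for 1 of 5 and lower for 1 in lymphoid, and higher for 2 of 6 and lower for 3 in myeloid nuclei. Medians of sex-linked genes were -0.07, -0.45, -0.26 and -0.70 in lymphoid, myeloid, megakaryocyte-side and erythroid-side nuclei.

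Against lists of matched expression, the MYC target median lay at percentile 100 of the drawn lists in all 4 classes. It did so in unnamed clusters 1, 2 and 6 too, with 0 of 55 targets called in cluster 2, so this was not particular to the 4 classes. The interferon response median lay at percentile 0.02 in lymphoid nuclei and 0 in the other progenitor classes. Mitochondrially encoded genes, which took from 9.22% to 24.6% of the UMIs between barcode sets, had their highest median beside the highest MYC target median, in erythroid-side nuclei. Unnamed cluster 6 had a mitochondrial median of 1.05 as well, and a MYC target median of 0.24 with 1 of 45 targets higher. The random lists matched to these targets had a median of -0.31 in cluster 6, as did all its measured genes. A link between mitochondrial share and MYC targets was not tested.

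**Figure D2:**
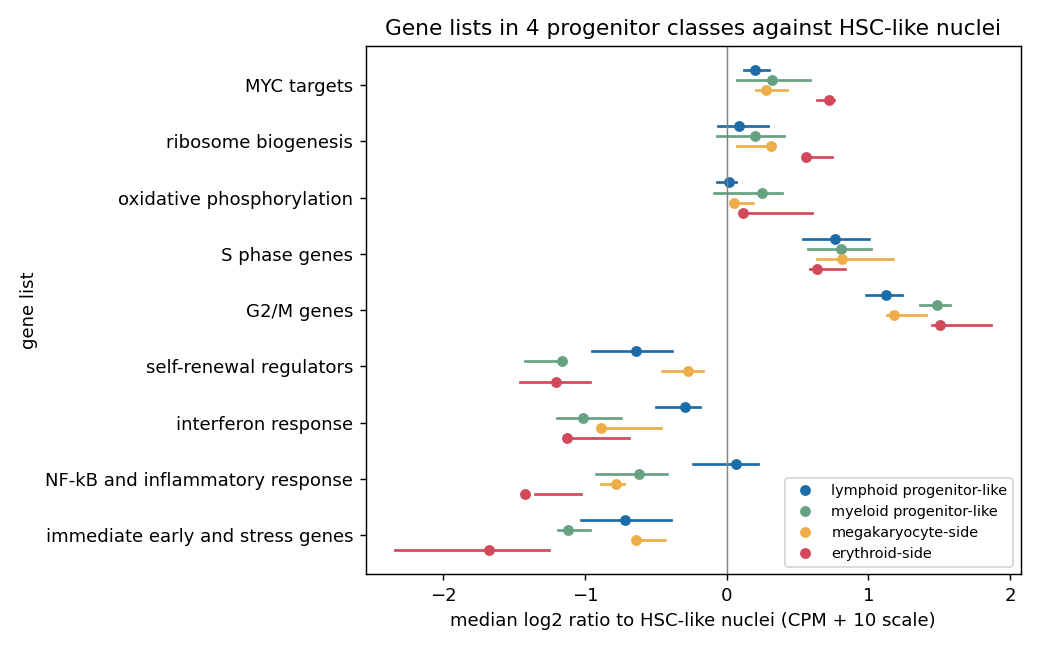
Median log2 ratio (CPM plus 10) of selected gene lists in 4 progenitor classes against HSC-like nuclei. Points are values over the whole table, and lines run from the lowest to the highest median of single barcode sets. MYC targets had a median of 0.72 and the interferon response list of -1.13 in erythroid-side nuclei.

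Over the whole table, and as CPM over all UMIs, Myc was at similar levels in HSC-like, myeloid, megakaryocyte-side and erythroid-side nuclei. Myc (chromosome 15, 61985341 to 61990361, GRCm38.p6) was at 48.2 CPM (42.1 to 55.0) in HSC-like nuclei, 44.8 in myeloid, 46.8 in megakaryocyte-side and 47.6 in erythroid-side nuclei. In lymphoid nuclei it was at 62.5, a ratio of 1.30 (1.09 to 1.55), but in set 3 it was at 44.0 against 45.5 CPM. The erythroid-side ratio of 0.986 (0.816 to 1.19) pooled sets that went both ways. Mitochondrially encoded genes took 27.6% of UMIs in erythroid-side and 13.3% in HSC-like nuclei, which lowers this ratio. Myc alone was not rescaled to non-mitochondrial UMIs. In sets 1 to 4 Myc was at 44.7, 70.4, 36.1 and 70.9 CPM in erythroid-side nuclei and at 51.2, 57.1, 45.5 and 45.0 CPM in HSC-like nuclei. Mycn, its paralog (chromosome 12, 12936093 to 12941836), was at 25.2 CPM (20.8 to 30.3) in HSC-like and 25.05 in megakaryocyte-side nuclei, and lower in lymphoid (5.52), myeloid (1.30) and erythroid-side nuclei (0.618, from 3 counts, a ratio of 40.8 with an interval of 13.6 to 201). In HSC-like nuclei of barcode sets 1 to 4 it was at 42.5, 37.1, 10.6 and 21.6 CPM. Fbxw7 (chromosome 3, 84814990 to 84979198), which encodes the ubiquitin ligase subunit that recognises MYC phosphorylated at threonine 58, was at 173 CPM in HSC-like, 215 in lymphoid, 223 in myeloid, 207 in megakaryocyte-side and 174 in erythroid-side nuclei. Of the MYC network list, members called lower were 1 of 17 in lymphoid (Mycn), 2 of 18 in myeloid (Mycn and Mxd4), 1 of 16 in megakaryocyte-side (Mxd4) and 4 of 17 in erythroid-side nuclei (Mycn, Ppp2r5a, Usp28 and Mnt). Called higher were Skp2 in megakaryocyte-side and Gsk3a in erythroid-side nuclei. Mxd4 was at 10.3 against 52.0 CPM in erythroid-side nuclei (5.05-fold lower, 3.71 to 6.99) but was not called. In set 2 it went the other way, at 37.9 CPM from 7 counts against 32.9 CPM. The list's medians were 0.01, -0.09, -0.10 and -0.16, the last of which was 0.09 over non-mitochondrial UMIs.

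**Figure D3:**
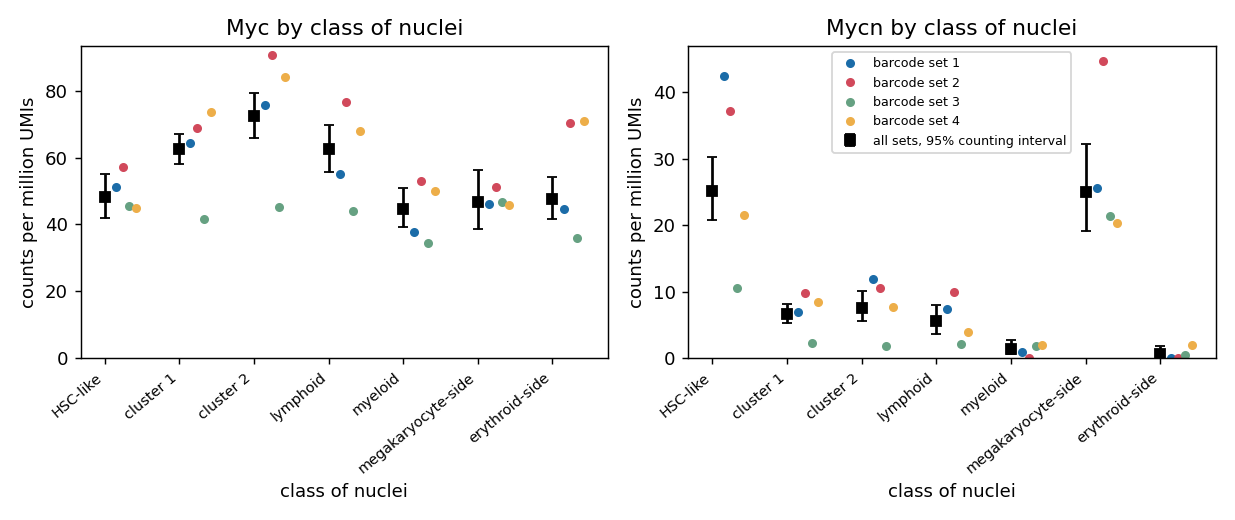
Levels (CPM) of Myc and Mycn in HSC-like nuclei, progenitor classes and the unnamed clusters led by Neil3 and by Vldlr. Shown are 95% Poisson intervals, with the 4 barcode sets as points. Over the whole table Myc was between 44.8 and 62.5 CPM in the 5 named classes, while Mycn was at 25.2 CPM in HSC-like and 1.30 CPM in myeloid progenitor-like nuclei.

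At 2000 UMIs per nucleus, among HSC-like nuclei and the 4 progenitor classes cell cycle genes were least often detected in HSC-like nuclei, 83.7% with G2/M genes (81.2 to 86.1%) and 67.4% with S phase genes. HSC-like G2/M shares ran from 77.7% to 90.4% in single barcode sets. In set 2 the erythroid-side share, of 13 nuclei, was lower than the HSC-like one, at 84.6% against 90.4%. Over all sets the shares were 94.2% and 87.5% in lymphoid, 99.2% and 92.4% in myeloid, 95.6% and 92.3% in megakaryocyte-side, and 99.006% and 90.9% in erythroid-side nuclei. The immunoglobulin-led nuclei gave 63.7% and 30.8%, but all 5 of them from set 4 had G2/M genes, with a median of 17, so they are no clean background for these shares. The shares were close to their ceiling, and the median number of G2/M genes separated the classes more clearly: 2 in immunoglobulin-led, 3 in HSC-like, 5 in lymphoid and megakaryocyte-side, 9 in myeloid and 10 in erythroid-side nuclei. At median depths before thinning of 3428 UMIs in HSC-like and 3215 in immunoglobulin-led nuclei, no share was read as a share of dividing cells. Left out for under 2000 UMIs were 651, 7, 411 and 91 nuclei of barcode sets 1 to 4.

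The large unnamed clusters met no marker list. Cluster 1, with 1694 nuclei (19.5%), was led by Neil3, Depdc1b, Cep55, Efcab11 and Mdga1, had G2/M genes in 99.9% of nuclei (a median of 11 genes) and held 48 of 51 G2/M genes higher than HSC-like nuclei, with Top2a at 889 against 96.7 CPM. Of its nuclei 11.3% carried the highest doublet scores. Cluster 2, with 1663 nuclei (19.1%), was led by Vldlr, Adgrl4, Pim1, Rgs1 and Ctla2a. It had Cd48, a gene whose protein is absent from the surface of the most primitive stem cells, at 65.0 against 22.6 CPM. The cell cycle kinase gene Cdk6 was at 2015 against 931 CPM. In this cluster 0 of 43 G2/M genes were called, while S phase genes were higher for 7 of 42 and lower for 0 (median 0.36). Myc was at 62.5 CPM in cluster 1 and 72.4 in cluster 2, and Mycn at 6.58 and 7.59. Cluster 6, with 599 nuclei (6.88%), was led by Gm15564, Lars2, Gm48099, Rpl38 and Cdk8, at a median of 2025 UMIs with 30.7% mitochondrial.

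RNA of mature cells was found in HSC-like nuclei at levels that differed between barcode sets 1 to 4. The immunoglobulin gene Igkc was at 273, 100, 545 and 26.9 CPM, the neutrophil gene S100a9 at 22.9, 2.86, 37.4 and 1.17 CPM, and the globin gene Hbb-bs at 16.3, 1.43, 25.2 and 0.584 CPM. In the immunoglobulin-led nuclei, of which the sets held 56, 2, 97 and 5, Igkc was at 37172, 158005, 37019 and 23519 CPM. The ribosomal-repeat-like transcript Gm42418 took 8.67%, 2.68%, 9.09% and 3.35% of all UMIs.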

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

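The sex-linked shares were measured without a comparison in mind, the reading of the interferon tests per class, and against the value each cause needed, was chosen after their values were seen, and the other tests here were written down before their results.

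Xist, transcribed from the inactive X chromosome of females, and Y-linked genes were both found in every barcode set, although their shares of nuclei entered no comparison. They stood out because their shares lay above the limit that a count of 0 allows, which was 0.128%, 0.420%, 0.128% and 0.140% in sets 1 to 4, a bar that nearly any detected share passes. At 2000 UMIs per nucleus, Xist without a Y-linked gene was found in 64.9%, 43.0%, 49.0% and 27.4% of nuclei. A Y-linked gene without Xist was found in 15.5%, 31.5%, 26.8% and 46.9%, and both together in 4.86%, 7.003%, 4.56% and 7.52%. Both together were found in 19.6% of the nuclei with the highest doublet scores and in 4.88% of the others.

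Clusters followed the barcode sets when set means were kept, with a Cramer's V of 0.341. The tables argue against 3 explanations, each taken alone as the whole cause, which would have brought V to 0.2 or below. With every nucleus thinned to 1000 UMIs V was 0.338 (0.333 to 0.349), which argues against depth, and without 437 mature cell and immunoglobulin genes it was 0.339 (0.331 to 0.352), which argues against free RNA of those genes. Without 92 ribosomal and repeat-like transcripts it was 0.306 (0.299 to 0.317), below the interval of 0.334 to 0.353 with all of them kept. A part of these transcripts in the pattern was therefore not excluded, and causes acting together were not tested. The genotype, the replicate and the preparation of each set stay open, since no set could be tied to a sample.

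The interferon response list was lower in myeloid, megakaryocyte-side and erythroid-side nuclei than in HSC-like nuclei. For the class closest to 0 all 3 values lay past the bound written beforehand, -0.6, but their intervals did not, so each class was read afterwards against the -0.4 or above that each needed as the whole cause. The tables argue against gene length, with medians of -0.88 (-1.20 to -0.71) in myeloid, -0.82 (-0.87 to -0.50) in megakaryocyte-side and -0.92 (-1.26 to -0.78) in erythroid-side nuclei once its trend was subtracted, and against a few HSC-like nuclei, with -0.85 (-1.17 to -0.49), -0.69 (-0.80 to -0.52) and -0.98 (-1.14 to -0.65) without the 10% with the highest interferon share. At equal numbers of G2/M genes, 356, 390 and 205 nuclei per class were left in the myeloid, megakaryocyte-side and erythroid-side comparisons. They measured 18, 20 and 13 members instead of 25, 26 and 26. For the members left, the median of -1.02 (-1.33 to -0.75) argues against the number of detected G2/M genes as the whole cause in myeloid nuclei. That number stays open as a cause in megakaryocyte-side (-0.72, -0.89 to -0.24) and erythroid-side nuclei (-1.11, -1.53 to -0.32). S phase genes were not matched, so cell cycle stays open in all 3 classes, and no biological explanation was tested.

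MYC targets were higher in erythroid-side than in HSC-like nuclei while Myc, over all UMIs and pooled over sets that went both ways, had a ratio of 0.986. At equal numbers of G2/M genes, with 205 nuclei per class, and without 2 cycle genes, only 39 members were measured instead of 55. Their median was 0.76 (0.51 to 1.01). With the gene length trend subtracted the median was 0.80 (0.51 to 0.94) over all 55. Both medians lay above the bound of 0.5. This argues against the number of detected G2/M genes, for those 39 members, and against length as the whole cause. S phase genes were not matched. The UMIs used for the match included mitochondrial ones, 27.6% in erythroid-side and 13.3% in HSC-like nuclei, so cell cycle stays open. The clustering used 0 of the 55 members as markers or variable genes, so it did not choose them directly. Leaving such genes out removed nothing, so the median of 0.72 (0.42 to 0.83) could not change and decides nothing. A choice through genes that vary with these members was not tested. Higher Myc in erythroid-side nuclei stays open in sets 2 and 4 and over non-mitochondrial UMIs, to which Myc was not rescaled. No biological explanation was tested.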

How the results depend on the processing

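No paired analysis was possible because no barcode set is tied to a genotype or replicate. The alternatives fixed for comparing genotypes (other tools, normalizations and filters on low counts) were not run, and the one for log-normalised values had no use with raw counts. Keeping set means, leaving out gene-list genes, doublets, nuclei over 40% mitochondrial or a barcode set, and the non-mitochondrial scaling were tests chosen only after the data were seen. The cause was not tested for any value that moved.

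MYC target medians in all 4 classes, and interferon medians in myeloid, megakaryocyte-side and erythroid-side nuclei, kept their sign in all 18 alternatives. For erythroid-side MYC targets, leaving out markers and variable genes removed 0 members, so that alternative could not differ. Of 24 list medians 5 took the other sign somewhere, in 13 of 426 values. Counts of genes higher or lower stayed within 1.5 times the reported count in 66 and 67 values and passed it in 2 and 1. Shares moved beyond their interval in 43 values and stayed within it in 37. The number of clusters ranged from 16 to 23.

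Shares of nuclei are given here in percent. At resolution 0.4 the HSC-like share was 9.04 and the lymphoid interferon median -0.10. At resolution 1.2 the megakaryocyte-side share was 8.61 and its oxidative phosphorylation median reversed to -0.00297. With 1000 variable genes the HSC-like, lymphoid and megakaryocyte-side shares were 7.99, 10.3 and 7.499, and the lymphoid interferon median -0.13. With 4000 the lymphoid, myeloid and megakaryocyte-side shares were 14.5, 7.79 and 5.37. With 15 components the HSC-like, lymphoid, myeloid and megakaryocyte-side shares were 10.2, 12.4, 7.99 and 8.59, and the erythroid-side MYC target and interferon medians 0.78 and -1.13. With 50 the lymphoid, myeloid and megakaryocyte-side shares were 14.0, 7.34 and 8.29, and the megakaryocyte-side MYC target median 0.19.

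Without nuclei under 500 genes the lymphoid and myeloid shares were 13.7 and 7.53, and the erythroid-side interferon median -1.14. Without cell cycle genes the lymphoid and megakaryocyte-side shares were 10.1 and 9.65, the lymphoid interferon median -0.13 and the megakaryocyte-side MYC target median 0.21. With set means kept the HSC-like and lymphoid shares were 6.26 and 8.27 and the lymphoid interferon median -0.0775. Without gene-list genes the HSC-like, lymphoid and megakaryocyte-side shares were 8.88, 10.3 and 8.93, the lymphoid interferon median -0.0620 and the megakaryocyte-side MYC target median 0.18. Without the highest doublet scores the HSC-like and lymphoid shares were 13.9 and 14.0 and the erythroid-side interferon median -1.23. Without nuclei over 40% mitochondrial the HSC-like and erythroid-side shares were 9.78 and 5.12, the lymphoid interferon median -0.15 and the erythroid-side MYC target median 0.76. Over non-mitochondrial UMIs the erythroid-side MYC target median was 0.97, with 1758 genes higher.

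Shares of nuclei with G2/M genes in HSC-like, lymphoid, myeloid, megakaryocyte-side and erythroid-side nuclei were 53.7, 74.8, 90.2, 76.5 and 95.1 at 1000 UMIs, and 63.5, 84.9, 96.4, 87.4 and 97.0 with at least 3 genes. Without thinning they were 94.0 in HSC-like, 97.6 in lymphoid and 100 in erythroid-side nuclei. With each barcode set left out, the HSC-like share ranged from 9.60 to 14.6, the lymphoid from 11.5 to 17.1 (without set 3), the myeloid from 7.51 to 13.5 (without set 2), the megakaryocyte-side from 5.71 to 9.18 (without set 1) and the erythroid-side from 4.57 to 6.64. The HSC-like G2/M share ranged from 82.8 to 86.7, the erythroid-side MYC target median from 0.71 to 0.78 and its interferon median from -1.22 to -0.98. The lymphoid interferon median ranged from -0.45 to 0.0115, reversed without set 2, where lymphoid genes higher and lower were at their lowest (366 to 868 and 618 to 1033). The 1.5-fold rule found 58% to 72% of simulated 2-fold increases and 46% to 70% of 2-fold decreases, and whether depth caused the misses was not tested.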

Other observations

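These values were chosen after they were seen, and no tests were run on them. Members of the MYC network went both ways between small classes named by mature cell lists and HSC-like nuclei. Mycl, the MYC paralog known from dendritic cells (chromosome 4, 122995588 to 123002490), was at 32.2 CPM (20.6 to 47.9, 24 counts) in monocyte, macrophage and dendritic cell-like nuclei and at 0 of 4560876 UMIs in HSC-like nuclei, which allows up to 0.658 CPM. Mxd1, which encodes a MAX partner that opposes MYC in differentiating cells, was at 217 CPM (156 to 295) in neutrophil-like and 140 CPM (101 to 190) in erythroid cell-like nuclei against 27.4 CPM in HSC-like nuclei. Mxi1, of the same family, was at 328 CPM (266 to 399) in erythroid cell-like nuclei against 64.2. Mga was lower in both classes than in HSC-like nuclei, at 106 (64.8 to 164) and 80.2 (51.4 to 119) against 296 CPM. Mxd4 was at 15.9 and 13.4 against 52.0 CPM, and Usp28 at 10.6 and 10.03 against 39.5 CPM. The values of Mxd4 and Usp28 in these classes rest on 2 to 4 counts each. In neutrophil-like nuclei their intervals were 3.28 to 46.5 and 1.28 to 38.3 CPM. Both overlapped the HSC-like intervals of 45.6 to 59.0 and 33.9 to 45.7 CPM. Nearly all nuclei of both classes came from barcode sets 1 and 3, while the HSC-like values pool all 4 sets. Fbxw7 was at 699 CPM (635 to 767) in the immunoglobulin-led nuclei, and at 531, 557, 783 and 627 CPM in the sets, while Myc was at 16.0 CPM (7.68 to 29.5) there.

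Of the HSC-like nuclei, 49.7% were also HSC-like with set means kept and 62.3% with 1000 variable genes. The same barcode sequence occurred in more than 1 set for 36 barcodes.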
